A study of Mus musculus with 52 samples.

How the data were processed

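Poly(A) RNA was sequenced from spinal cord, cerebral cortex and skeletal muscle of mice. Per the labels, RNA was isolated with a Qiagen kit, libraries were made with the Kapa mRNA HyperPrep kit and paired ends were read on a NovaSeq. In each tissue there were 3 arms: wild-type FVB/NJ mice given vehicle, mice transgenic for mutant human PFN1 given vehicle, and transgenic mice given an AAV that encodes an artificial microRNA (amiR) against Atxn2. No arm received a control vector. Whether transgenic and wild-type mice differ in more than the transgene was not tested, so a change with the transgene means a difference between these arms. The 52 libraries were 18 of spinal cord, 17 of cortex and 17 of muscle, with 6 per arm except 5 in wild-type cortex and 5 in vehicle-treated transgenic muscle. By the labels, 41 libraries came from mice of 36 weeks and 11 from transgenic mice of 38 or 39 weeks. In spinal cord all 4 older mice were females, and in muscle all 3, so sex and age are partly confounded among the transgenic arms of those tissues. The labels do not tie the tissues to animals, so the tissues were treated as separate samples.

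The deposited table holds RSEM expected counts per gene, not normalized, per the labels and the values. The tools credited per the submitters' processing notes are bcl2fastq 2.20, STAR 2.7.2d, RSEM 1.3.2 and DESeq2 1.34.0, with GRCm38 and GRCh38 as genome builds. The table has 55510 lines: 55401 mouse genes, of which 55141 matched a symbol in the GENCODE M21 annotation, 1 human gene (PFN1), 16 vector elements and 92 ERCC spike-ins. No ERCC line and no AAV2 ITR line held a count, and 12 vector elements did in at least 1 library. At most 0.167% of a library's counts lay outside mouse genes. The annotation release used by the authors is not given in the sources used here. No other column of per-sample values was found in the table.

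Counts were rounded to whole numbers. Total counts per library ranged from 66.5 to 111.9 M (mean 84.6 M). Within a group, the chi-square per gene between libraries was at least 13, above counting error as an average over genes, so every interval and test rests on the spread between libraries, and floors from a count of 0 cover counting error only. Expression of Xist and of Y-linked genes matched the labelled sex in 52 of 52 libraries. In 4 spinal cord libraries the title and the library name give opposite treatments; vector counts matched the title in 4 of 4, and the titles were used. The labels do not say that replicate numbers pair the samples, and no pairing was assumed: library deviations from their group mean correlated between like-numbered libraries of 2 arms at r from −0.12 to 0.30 in spinal cord, −0.30 to 0.49 in cortex and −0.21 to 0.42 in muscle. With the sex of the libraries removed as well, r lay between −0.33 and 0.33.

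Each tissue was fitted apart with edgeR 4.0.16 (R 4.3.3): TMM scaling, filterByExpr, a quasi-likelihood model with arm and sex, and quasi-likelihood F tests. P-values were adjusted over all genes tested in the tissue (Benjamini-Hochberg), with a threshold of 0.05. This left 20307 genes in spinal cord, 20278 in cortex and 16949 in muscle. Log2 fold changes are from this model, each with its standard error (SE), and CPM of groups of mouse genes are means ± SD after TMM scaling unless called unscaled. CPM of vector elements, of human PFN1 and of single libraries are unscaled. For Atxn2, mouse Pfn1 and human PFN1, an exact permutation test on the log2 of unscaled CPM (pseudocount 0.5) was run as well. Its smallest possible p is 0.00216, for 6 against 6 and for 6 against 5. The differences between tissues and between sexes were tested as interaction terms, those between tissues in a joint model of 22316 genes.

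Before the data were examined, 49 gene lists for cell types and processes were written, and those that apply were tested in each tissue: 42 in spinal cord, 41 in cortex and 32 in muscle. The tests were camera from limma 3.58.1 with a preset correlation between genes of 0.01, camera with an estimated correlation, and fry, each adjusted over all lists and comparisons of the tissue. The samples, comparisons, models, alternatives and the rule for naming genes were fixed at the same point. By that rule the text names Atxn2, mouse Pfn1 and human PFN1; for each comparison the 10 largest rises and the 10 largest falls among called genes with a mean of at least 1 CPM, without predicted or clone-named models; and up to 4 called members of each list with the smallest adjusted p. A gene outside the rule is said to have been chosen after its values were seen. For each named gene, the libraries of the first arm that lie beyond the mean of the second arm on the side of the change were counted. Most of these genes were named for a called change in the same libraries, so the count describes that change and does not test it.

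The transgenic minus wild-type change and the treated minus vehicle change share the vehicle-treated transgenic libraries, which alone gives a negative correlation over genes. This was addressed by simulation (50 simulations with no true change between any arms) and by using separate sets of the vehicle-treated libraries for each change. After the results were seen, 20 simulations that kept the measured transgenic minus wild-type change and set the treatment change to 0 were added, and the separate sets were also fitted with edgeR. The simulations draw genes independently of each other. Recovery was tested on simulated data with 200 changed genes, 100 at each of 2 sizes, built on the measured means and spreads. At a true log2 change of 0.5, 64 of 100 genes were recovered for transgenic against wild-type mice in spinal cord, 62 in cortex and 63 in muscle. For treated against vehicle-treated mice the numbers were 74, 50 and 59. At a true log2 change of 1, between 88 and 96 of 100 were recovered over these 6 settings, with 5 to 10 false calls.

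The alternatives were RLE scaling, the DESeq2 1.42.0 Wald test, limma-voom, no filter beyond 1 count, a filter of at least 1 CPM in at least 5 libraries, no sex term, RNA integrity number (RIN) as a covariate, only the 2 arms compared, replicate number as a block, leaving out mice older than 36 weeks, leaving out each library in turn, and, for the 4 libraries with conflicting labels, following the library names or leaving them out. Short sequences in transcripts were counted with Python 3.11.15 (numpy 2.4.6, scipy 1.17.1, pandas 2.3.3). All 7-mers present in at least 20 genes (16377 of 16384 in spinal cord and cortex, 16364 in muscle) were scanned in annotated 3′ UTRs of at least 50 bases from genes with at least 2 CPM, with 200 permutations. Figures were drawn with matplotlib 3.10.9. Some genes that the naming rule selects are not reported here. Sequence reads were not used here, and neither splice forms nor the amiR itself were measured.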

Results

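The libraries come from mice that carry mutant human profilin-1 (PFN1), an actin-binding protein mutated in familial amyotrophic lateral sclerosis (ALS), and from wild-type FVB/NJ mice. Transgenic mice received vehicle or an AAV that encodes an artificial microRNA (amiR) against Atxn2. Spinal cord (18 libraries, 73.2 to 109.3 M counts each), cortex (17 libraries, 67.5 to 90.4 M) and skeletal muscle (17 libraries, 66.5 to 111.9 M) were sampled with n = 5 or 6 per arm. Between 21246 and 27674 genes had a count above 0 in a library. On the first principal component of spinal cord (34.6% of the variance), wild-type libraries lay between −53.8 and −41.5 and vehicle-treated transgenic libraries between 30.1 and 41.6. Treated transgenic libraries spread from −7.4 to 40. In muscle this component held 46.1% and also parted wild-type from transgenic libraries, while in cortex (20.4%) the arms overlapped.

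**Figure D1:**
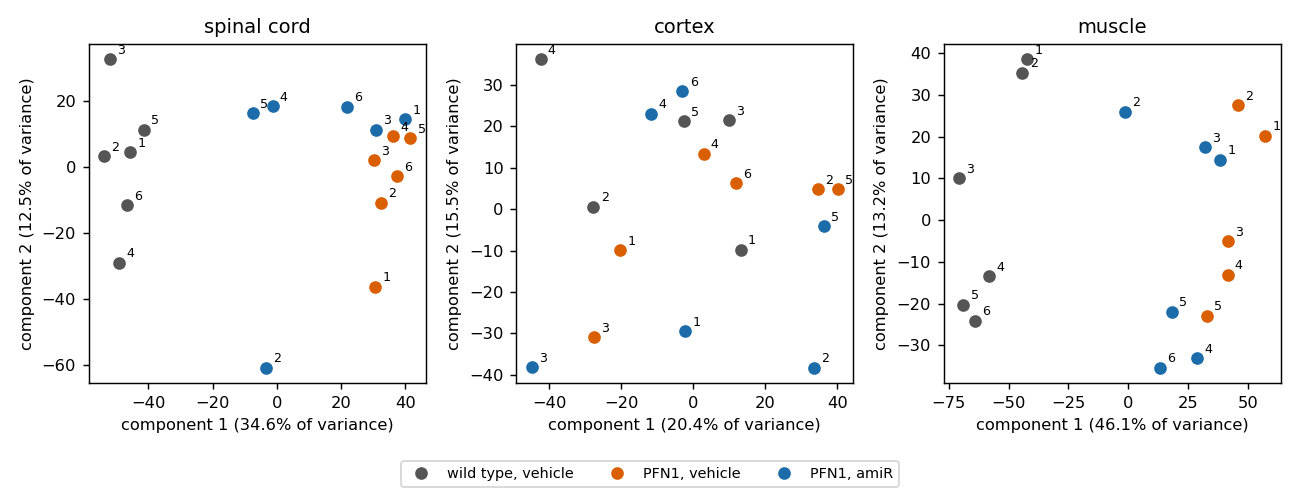
First and second principal components of the libraries of each tissue, by arm. The share of the variance of each component is given on its axis.

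Atxn2, the target of the amiR, encodes ataxin-2, an RNA-binding protein linked to ALS. In spinal cord its level was 123.4 ± 5.72 CPM in wild-type, 106.3 ± 2.68 in vehicle-treated and 72.54 ± 0.859 in treated transgenic mice (n = 6 each). With treatment it fell, by a log2 change of −0.55 (SE 0.03, adjusted p = 8.7e-08 by edgeR), in 6 of 6 libraries. On unscaled CPM the difference was −33.9% (exact permutation p = 0.00216, the smallest possible, adjusted p = 0.00907). Against wild type, treated spinal cord held less Atxn2 by −0.77 (SE 0.03, adjusted p = 2.5e-10, 6 of 6 libraries), and vehicle-treated transgenic spinal cord differed from wild type by −0.22 (SE 0.03, adjusted p = 9.45e-05, 6 of 6 libraries). On unscaled CPM the latter difference was smaller, −0.12 (exact permutation p = 0.00433, adjusted p = 0.0101). In cortex Atxn2 lay below the vehicle mean in 6 of 6 treated libraries. That difference of −0.27 (SE 0.07) did not pass by edgeR (adjusted p = 0.189), passed by DESeq2 (adjusted p = 0.0427), and on unscaled CPM was −18.7% (exact permutation p = 0.00433, adjusted p = 0.0101). In muscle the difference was 0.04 (SE 0.06, adjusted p = 0.76), and −0.10 on unscaled CPM (exact permutation p = 0.113). Transgenic against wild-type muscle differed by −0.07 after TMM scaling (adjusted p = 0.353) but by 0.26 on unscaled CPM (exact permutation p = 0.00433, adjusted p = 0.0101), so the sign there depends on the scaling. The treatment effect on Atxn2 differed between spinal cord and muscle by −0.62 (SE 0.08, adjusted p = 2.18e-05) and between cortex and muscle by −0.33 (SE 0.08, adjusted p = 0.0232). Between spinal cord and cortex the difference of −0.28 did not pass (adjusted p = 0.146).

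Vector transcripts followed the same tissues. WPRE, a stabilizing element at the 3′ end of the vector transcript, was counted at 52.1 ± 15.0 unscaled CPM in treated spinal cord, 41.8 ± 15.2 CPM in treated cortex and 0.0303 ± 0.0144 CPM in treated muscle, where libraries held 1 to 5 counts. Vehicle-treated and wild-type libraries held 0 counts, except 1 count in 1 cortex library (vehicle-treated transgenic replicate 6). The miRE scaffold of the amiR was at 12.8 ± 3.6 CPM in treated spinal cord and 9.41 ± 3.46 CPM in treated cortex.

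**Figure D2:**
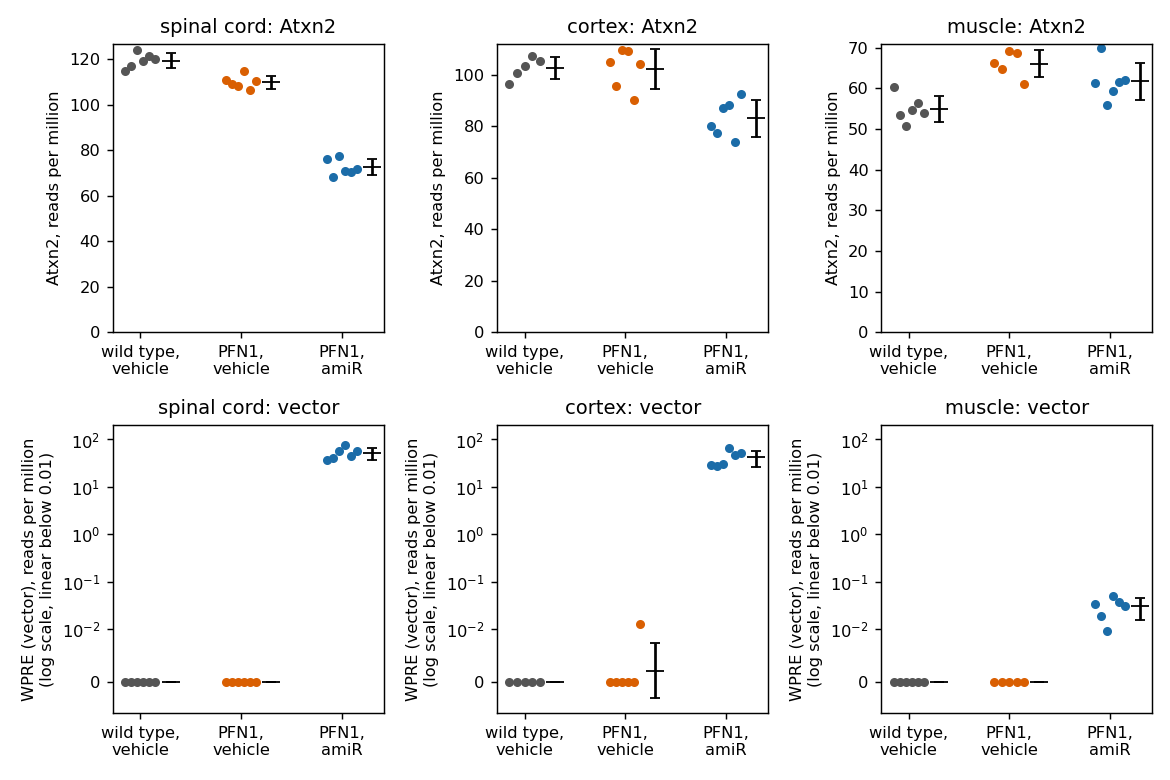
Atxn2 and WPRE in each library, in unscaled CPM, by tissue and arm.

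Human PFN1 was read in transgenic libraries of every tissue: 686.9 ± 43.7 unscaled CPM in spinal cord, 1027 ± 182 in cortex and 236.1 ± 50.9 in muscle of vehicle-treated mice, against at most 0.0143 CPM in wild-type libraries. With treatment it was 848.9 ± 228, 1227 ± 235 and 244.3 ± 45.9 CPM, and the differences did not pass (exact permutation p = 0.147, 0.13 and 0.736). Mouse Pfn1 rose in transgenic spinal cord by a log2 change of 0.45 (SE 0.06, adjusted p = 9.8e-06, 6 of 6 libraries), more than in cortex by 0.35 (SE 0.10, adjusted p = 0.0273), where the change of 0.09 did not pass. In muscle it was 0.19 (SE 0.08, adjusted p = 0.0605), while on unscaled CPM the difference was 0.51 (exact permutation p = 0.00216, adjusted p = 0.00907), so the call there depends on the scaling. Treatment did not move mouse Pfn1 past the threshold in spinal cord (−0.12, adjusted p = 0.206), cortex (0.08) or muscle (−0.03).

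In spinal cord of vehicle-treated transgenic mice, the program of disease-associated microglia was raised throughout. All 25 tested genes of this list rose (25 when adjusted over the list alone), with a median log2 change of 3.14 (camera adjusted p = 1.55e-42; adjusted p = 0.0608 with an estimated correlation). Among them were Cybb, a subunit of the phagocyte oxidase (4.37, SE 0.33), the galectin Lgals3 (4.25, SE 0.35), Ch25h, which makes 25-hydroxycholesterol (3.50, SE 0.28), and the lysosomal protease Ctsz (2.02, SE 0.16). Among the 10 largest rises were the proton pump subunit Atp6v0d2 (9.07, SE 0.94), the lysosomal glycoprotein Gpnmb (8.20, SE 0.78), the elastase Mmp12 (7.36, SE 0.73) and the protease inhibitor Cst7 (6.19, SE 0.57). Complement and MHC class I genes rose in 14 of 14 (14 when adjusted over the list alone; median 1.62), as with B2m (1.67, SE 0.12), C1qc (2.89, SE 0.24) and C3ar1 (4.09, SE 0.34). Of the 20 lists called in this comparison, this was the list whose call held with an estimated correlation (adjusted p = 0.0183). Homeostatic microglial genes such as Cx3cr1 (1.46, SE 0.14) rose in 9 of 12 (9 up and 1 down when adjusted over the list alone; adjusted p = 0.29 with an estimated correlation).

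Genes of astrocytes, of the interferon response and of T cells rose as well. Genes of reactive astrocytes rose in 17 of 20 (18 when adjusted over the list alone; median 1.73; adjusted p = 0.0608 with an estimated correlation), among them Timp1 (4.03, SE 0.24), the intermediate filament Vim (2.72, SE 0.22) and Socs3 (2.79, SE 0.26). Interferon-stimulated genes rose in 14 of 20 (14 when adjusted over the list alone; median 0.56), with Bst2 at 1.33 (SE 0.10) and Ifitm3 at 1.00; with an estimated correlation the adjusted p = 0.29. All 11 tested T cell genes rose (11 when adjusted over the list alone), such as Cd5 (2.16, SE 0.35) and Cd8a (2.79, SE 0.58), with a median of 1.94 and adjusted p = 0.232 with an estimated correlation.

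Neuronal transcripts fell beside these rises. Motor neuron genes fell in 16 of 18 (17 when adjusted over the list alone), with a median of −0.83 (adjusted p = 0.392 with an estimated correlation). They include Chodl (−1.97, SE 0.25) and Mmp9 (−1.14, SE 0.15), which mark fast motor neurons, and Esrrg (−0.66, SE 0.12), which marks the gamma type. Neurofilament and axonal transport genes fell in 10 of 12 (11 when adjusted over the list alone; adjusted p = 0.233 with an estimated correlation), with the neurofilament subunits Nefh at −1.11 (SE 0.15) and Nefl at −0.89 (SE 0.12), and the motor Kif5a at −0.53. Synaptic genes fell in 13 of 17 (13 when adjusted over the list alone; median −0.36), as did the complexin Cplx1 (−0.58, SE 0.06), and 5 of 11 genes of inhibitory neurons fell (5 when adjusted over the list alone), as did the glycine transporter Slc6a5 (−0.72, SE 0.08). With an estimated correlation the adjusted p = 0.29 for each of the last 2 lists. Genes of neuronal injury rose in 8 of 14 (10 when adjusted over the list alone; adjusted p = 0.494 with an estimated correlation), with Atf3 at 2.85 (SE 0.36) and Sprr1a at 4.47 (SE 0.73).

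Cholesterol synthesis was lowered along the whole pathway in transgenic spinal cord. All 20 genes fell (20 when adjusted over the list alone; median −1.19, camera adjusted p = 1.66e-18, adjusted p = 0.29 with an estimated correlation), including the demethylase Cyp51 (−1.27, SE 0.15) and the cyclase Lss (−0.97, SE 0.12). In all, edgeR called 7442 of 20307 genes, 3815 higher and 3627 lower; 1041 rises and 104 falls were over 2-fold. Of the 155 named genes counted for direction, 154 moved that way in 6 of 6 libraries. Leaving out any library gave 6682 to 7206 genes. Sex and age are partly confounded in this tissue.

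**Figure D3:**
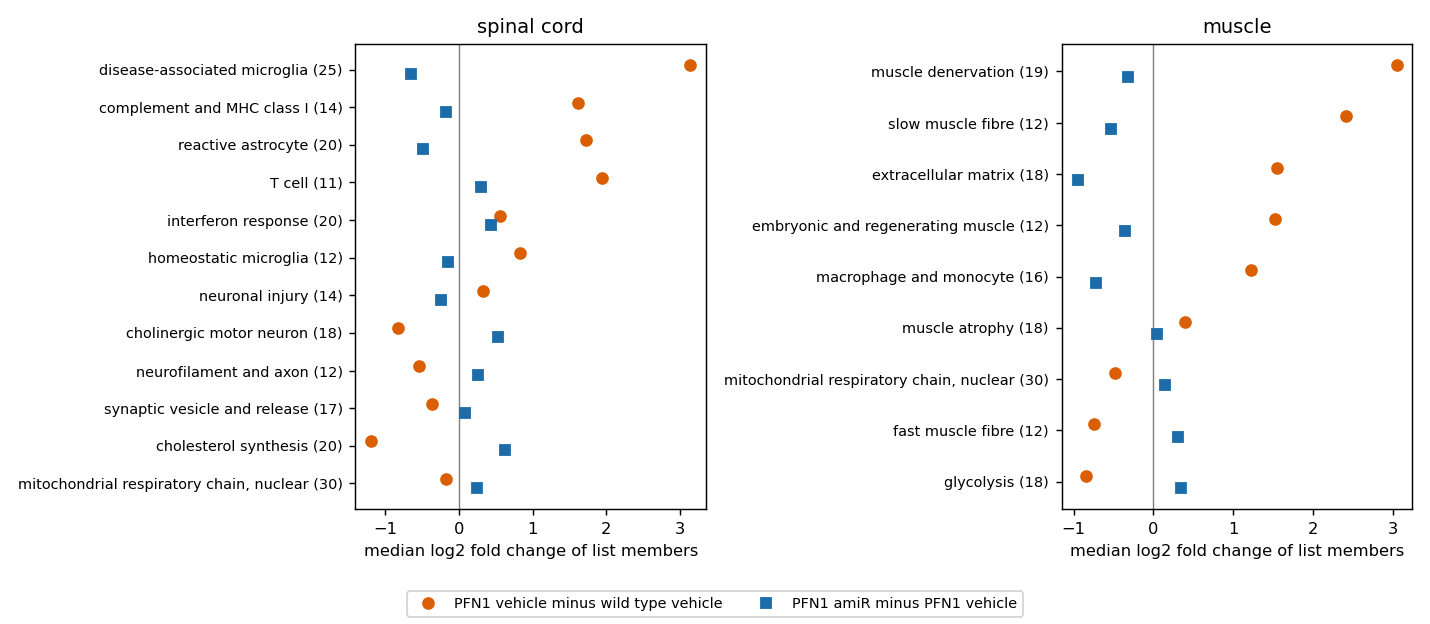
Median log2 change of selected gene lists in spinal cord and muscle, for transgenic minus wild-type mice and for treated minus vehicle-treated transgenic mice. Cortex and the other lists tested are not drawn.

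Treatment moved many of these genes in spinal cord the opposite way. Genes of disease-associated microglia fell in 6 of 25 (14 when adjusted over the list alone), with a median of −0.65 (adjusted p = 0.29 with an estimated correlation): the changes were −2.97 (SE 0.60) for Gpnmb, −1.22 (SE 0.30) for Lgals3 and −0.55 (SE 0.12) for the protease Ctsb. Lyz1 (−2.86, SE 0.52) and Atp6v0d2 (−2.41) were among the 10 largest falls; the call held in 22 of 24 alternatives for Gpnmb and Lyz1, 20 for Ctsb, 11 for Atp6v0d2 and 9 for Lgals3. Motor neuron genes rose in 5 of 18 (12 when adjusted over the list alone), with a median of 0.53 (adjusted p = 0.29 with an estimated correlation), including the motor axon filament Prph (1.23, SE 0.23), Chodl (0.99, SE 0.25), Chat, which makes acetylcholine (0.88, SE 0.19), and Mmp9 (0.57, SE 0.15). Treated replicate 4 stood apart from the other treated libraries for Prph and Chat (gap over range 0.674 and 0.803), and the call held in 21 of 24 alternatives for Prph, 18 for Chat, 11 for Chodl and 8 for Mmp9. Neurofilament and axonal transport genes rose in 5 of 12 (6 when adjusted over the list alone; adjusted p = 0.315 with an estimated correlation), with Nefm at 0.52, Nefh at 0.54 and Stmn2 at 0.34 (SE 0.07); the call held in 9 of 24 alternatives for Nefm and Nefh and in 21 for Stmn2. Cholesterol synthesis rose in 11 of 20 (19 when adjusted over the list alone; median 0.63, camera adjusted p = 5.78e-17, adjusted p = 0.29 with an estimated correlation), with Fdft1 at 0.87 (SE 0.19) and Sqle at 0.79 (SE 0.18).

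A few genes of energy metabolism rose with treatment. The share of counts from the mitochondrial genome was 11.8% in treated replicate 2, against 7.74 to 9.97% in the other treated and 6.87 to 8.44% in vehicle-treated libraries. Nuclear genes of oxidative phosphorylation rose in 5 of 30 (21 when adjusted over the list alone; adjusted p = 0.405 with an estimated correlation), such as Ndufa9 (0.37, SE 0.09), and 4 of 18 glycolytic genes rose (13 when adjusted over the list alone), such as Pgm1 (0.33). The mitochondrial genome gave mt-Nd5 (0.40, SE 0.09) as 1 of 13 (10 when adjusted over the list alone). For the last 2 lists the adjusted p = 0.392 with an estimated correlation. Reactive astrocyte genes gave 1 fall of 20, S1pr3 (−0.73, SE 0.19), with 12 when adjusted over the list alone and adjusted p = 0.29 with an estimated correlation.

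Some interferon-stimulated genes rose with treatment, 7 of 20 (10 when adjusted over the list alone; median 0.43; adjusted p = 0.266 with an estimated correlation), with Ifi44 at 1.3 (SE 0.24) and Oasl2 at 0.73 (SE 0.14). Among the largest rises were the MHC class II genes H2-Aa (1.45, SE 0.30), Cd74 (1.41, SE 0.26) and H2-Ab1 (1.28), and the interferon-inducible GTPases Gbp8 (2.86, SE 0.64), Iigp1 (1.58, SE 0.39) and Igtp (1.07). Of 11 T cell genes Cd8a rose (2.19, SE 0.37), with 2 when adjusted over the list alone and adjusted p = 0.308 with an estimated correlation.

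Over all genes, 1017 were called for treated against vehicle-treated spinal cord (588 higher, 429 lower), and 58 of the 67 named genes counted moved that way in 6 of 6 libraries, with 5 of 6 for Nefh, Fdft1, Sqle, Lss and 5 others. For 28 of the 67 the treated and vehicle-treated libraries did not overlap. Of these 1017, 729 had been called with the opposite sign in transgenic against wild-type mice, 43 with the same sign and 245 not at all. With separate vehicle libraries (20 splits) the medians were 60.5 genes called for treatment (28 to 930), 12 rises that fell (4 to 137), 15.5 falls that rose (5 to 207) and 8 of the same sign (2 to 130). The splits hold fewer vehicle libraries per change. The count depended on single libraries. It was 506, 599, 498, 527, 392 and 676 without vehicle replicates 1, 2, 3, 4, 5 and 6, and 2507, 553, 237 and 360 without treated replicates 1, 2, 4 and 5. It was 321 with RIN as a covariate (43 of 69 named genes no longer called, RIN reached 8.3 in treated and 7.7 in vehicle-treated libraries), 88 without mice older than 36 weeks and 0 when the 4 libraries with conflicting labels followed their library names (3019 at unadjusted p under 0.05). By that last setting alone, 0 of 68 named genes could be called in every alternative. Atxn2 was called in 23 of 24.

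How far treatment brought transgenic spinal cord back was measured gene by gene. Of the 7442 genes called for transgenic against wild-type mice, 6267 (84.2%) moved in the opposite direction with treatment. For the 1145 genes changed over 2-fold, the median share of the change that was undone was 23.6%. Both changes share the vehicle-treated libraries, which by itself favours opposite signs. In 20 simulations with no treatment change 59.1 to 61.1% moved the opposite way and 2.21 to 4.02% was undone. With separate vehicle libraries (20 splits) the values were 54.8 to 86.7% (median 80.4%) and 10.1 to 31% (median 22.1%). Over all genes the correlation of both fitted changes was r = −0.49. On log CPM, where the simulations were run, r was −0.60 and the covariance −0.0994, against r from −0.55 to −0.45 and a mean covariance of −0.0222 from shared vehicle libraries alone. With separate vehicle libraries for each change r was −0.44. Genes are not independent replicates, so no p-value is given.

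Treated spinal cord still differed from wild type in 5163 genes (2953 higher, 2210 lower). Disease-associated microglial genes remained higher in 25 of 25 (25 when adjusted over the list alone; median 2.60; adjusted p = 0.0768 with an estimated correlation), with Cst7 at 5.60 (SE 0.56), Mmp12 at 5.55 (SE 0.70) and Gpnmb at 5.23 (SE 0.73). Interferon-stimulated genes were higher in 20 of 20 (20 when adjusted over the list alone; median 1.04), T cell genes in 11 of 11 (11 when adjusted over the list alone; median 2.03) and complement and MHC class I genes in 13 of 14 (13 when adjusted over the list alone; median 1.51). These 3 calls held with an estimated correlation (adjusted p = 0.0279, 0.0227 and 0.00966). Motor neuron genes were lower in 3 of 18 (3 when adjusted over the list alone; adjusted p = 0.747 with an estimated correlation), neurofilament and axonal transport genes in 7 of 12 (7 when adjusted over the list alone; adjusted p = 0.29) and cholesterol synthesis in 13 of 20 (17 when adjusted over the list alone; adjusted p = 0.431). Fabp4 had the largest rise among named genes of this comparison (7.66, SE 2.69, adjusted p = 0.0484), but lay above the wild-type mean in 3 of 6 libraries, with replicate 2 far above the others (gap over range 0.999), and was called in 9 of 24 alternatives. Of the 7442 genes called for vehicle-treated transgenic against wild-type mice, 4210 were still called against wild type with the same sign and 3228 were not called, and 949 genes were called only in treated mice. Leaving out any library gave 4343 to 5318 genes.

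In cortex few genes differed between transgenic and wild-type mice. The 5 genes called by edgeR were Prnp (2.2, SE 0.06, adjusted p = 1.65e-12), Thy1 (2.12, SE 0.18, adjusted p = 1.29e-05) and the pseudogene Lamr1-ps1 (chosen after its values were seen), all higher in 6 of 6 transgenic libraries, and Nbdy and Mnat1, both lower in 6 of 6. Nbdy, which encodes a microprotein of the mRNA decapping complex, held 687 to 949 counts in wild-type libraries and 11 counts over all 12 transgenic libraries. Lamr1-ps1 held 1 count over the 5 wild-type libraries. Mnat1, a subunit of the CDK-activating kinase, differed by −0.47 (SE 0.07, adjusted p = 0.0277) and was called in 7 of 21 alternatives. At unadjusted p under 0.05 there were 754 genes, and DESeq2 called 9 and limma-voom 7. Of 15 lists called, none held with an estimated correlation (0 by fry). Immediate early genes, induced by neuronal activity, had a median of −0.90 (3 falls when adjusted over the list alone and 0 over all genes; adjusted p = 0.286 with an estimated correlation). Leaving out any library gave 4 to 5 genes.

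For treatment in cortex 4 genes were called, of which Cxcl9 and Ighg2b were chosen after their values were seen: Atxn7l3b (−0.39, SE 0.04, adjusted p = 0.00377) and the methylmalonate semialdehyde dehydrogenase Aldh6a1 (−0.31, SE 0.04, adjusted p = 0.0205) fell, and the chemokine Cxcl9 and the antibody gene Ighg2b rose, from means of 0.0176 to 0.331 CPM and of 0.0804 to 1.47 CPM. The vehicle mean of Cxcl9 lies under 3 counts per library, so no fold is given. By edgeR no gene of glycolysis passed over all genes (11 up when adjusted over the list alone; median 0.19; adjusted p = 0.214 with an estimated correlation). Actin and profilin genes also gave none (10 up and 1 down when adjusted over the list alone; median 0.15; adjusted p = 0.0936 with an estimated correlation). At unadjusted p under 0.05 there were 2297 genes, and DESeq2 called 340 and limma-voom 4. No gene was called with only the 2 arms fitted or without mice older than 36 weeks; the call held in 20 of 22 alternatives for Atxn7l3b and in 12 for Aldh6a1. The count was 74 without vehicle replicate 3 and 9 without treated replicate 2. It was 2 without vehicle replicate 4 or 6 or treated replicate 5, and 1 without vehicle replicate 1 or treated replicate 3, 4 or 6.

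Against wild type, treated cortex differed in 244 genes (144 higher, 100 lower; 3703 at unadjusted p under 0.05). Actin and profilin genes rose in 5 of 18 (10 up and 1 down when adjusted over the list alone), and this call held with an estimated correlation (adjusted p = 0.0445): the cytoplasmic actins Actg1 (0.38, SE 0.06) and Actb (0.33), the depolymerizing factor Dstn (0.31) and Arpc2 of the branching complex (0.22) rose in all 6 libraries. Their calls held in 18 of 21 alternatives for Actg1, 10 for Dstn, 9 for Actb and 7 for Arpc2. Of 14 complement and MHC class I genes 2 rose (11 when adjusted over the list alone), C3ar1 (0.93, SE 0.19) and C4b (1.18, SE 0.27), and of 20 interferon-stimulated genes Ifi44 (0.93) and Cxcl10 (2.45) did (7 up and 1 down when adjusted over the list alone). For each of these lists the adjusted p = 0.286 with an estimated correlation, and Ifi44 and Cxcl10 were each called in 5 of 20 alternatives. C3ar1 was called in 10 of 21 and C4b in 7. The antibody chain Igkc (3.77, SE 0.72) was among the 10 largest rises and was called in 9 of 21 alternatives. Glycolysis rose in 4 of 18 (12 when adjusted over the list alone; adjusted p = 0.275 with an estimated correlation), with Aldoa at 0.30 (SE 0.05), and the proteasome in 3 of 27 (19 when adjusted over the list alone; adjusted p = 0.286), with Psmb7 at 0.23. Aldoa was called in 11 of 21 alternatives and Psmb7 in 7. Six4 (−1.72, SE 0.29) and the desaturase Scd1 (−0.89, SE 0.14) fell. The count rested on single libraries: 75, 11, 32, 19 and 21 without wild-type replicates 1 to 5 in order, and 369, 29, 28, 23, 16 and 55 without treated replicates 1 to 6 in order. DESeq2 called 1381 and limma-voom 184. With RIN as a covariate 11 genes were called and 36 of 42 named genes no longer were; RIN was 7.3 to 7.9 in wild-type and 7.7 to 8.3 in treated cortex.

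Muscle of vehicle-treated transgenic mice expressed genes that muscle induces when it loses its nerve. Denervation genes rose in 17 of 19 (17 when adjusted over the list alone; median 3.04; camera adjusted p = 1.48e-27, adjusted p = 0.133 with an estimated correlation): the growth factor Gdf5 (5.73, SE 0.36), the transcription factor Runx1 (4.40, SE 0.24) and the acetylcholine receptor subunit Chrnd (4.27, SE 0.27). Genes of embryonic and regenerating muscle rose in 10 of 12 (10 when adjusted over the list alone; adjusted p = 0.133 with an estimated correlation), such as the fusion factor Mymk (3.49, SE 0.37) and Myl4 (2.42, SE 0.27). Atrophy genes rose in 10 of 18 (10 when adjusted over the list alone; adjusted p = 0.272 with an estimated correlation), such as Cdkn1a (3.12, SE 0.22), the protease Ctsl (1.01, SE 0.06) and the ubiquitin ligase Fbxo30 (0.83). The keratins Krt8 (8.05, SE 0.69) and Krt18 (7.17) and the calcium pump inhibitor Sln (6.18, SE 0.49) were among the 10 largest rises.

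The fiber program shifted from fast to slow. Slow-fiber genes rose in 10 of 12 (10 when adjusted over the list alone; median 2.41; adjusted p = 0.31 with an estimated correlation), with the troponins Tnnt1 (4.31, SE 0.45) and Tnni1 (4.32, SE 0.46) and the slow calcium pump Atp2a2 (3.01). Fast-fiber genes fell in 10 of 12 and rose in 1 (the same numbers when adjusted over the list alone; median −0.75; adjusted p = 0.141 with an estimated correlation), including parvalbumin Pvalb (−1.71, SE 0.16), Actn3 (−1.29, SE 0.14) and the fast calcium pump Atp2a1 (−1.11, SE 0.11). Glycolytic genes fell in 13 of 18 and rose in 2 (2 and 13 also when adjusted over the list alone; adjusted p = 0.18 with an estimated correlation), with the glycogen phosphorylase Pygm at −1.27 (SE 0.11) and the phosphofructokinase Pfkm at −0.98 (SE 0.08). Oxidative phosphorylation fell in 29 of 30 (29 when adjusted over the list alone, median −0.48, adjusted p = 0.616 with an estimated correlation). On unscaled CPM Atxn2 (0.26) and mouse Pfn1 (0.51) lay higher in this comparison than after TMM scaling. The size of small changes in muscle such as this median thus depends on the scaling. Muscle enzymes of polyamine, one-carbon and creatine metabolism fell in 7 of 10 and rose in 2 (the same when adjusted over the list alone; adjusted p = 0.24 with an estimated correlation), with Smox at −2.49 (SE 0.29), Amd1 at −2.28 (SE 0.24) and the creatine kinase Ckm at −1.12. Mss51, a regulator of muscle metabolism (−3.08, SE 0.23) and Trnp1 (−5.33, SE 0.88) were among the 10 largest falls.

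Matrix and macrophage genes rose in the same libraries. Extracellular matrix genes rose in 18 of 18 (18 when adjusted over the list alone; median 1.55; adjusted p = 0.334 with an estimated correlation), with the protease inhibitor Timp1 (4.67, SE 0.34), the collagen cross-linker Lox (2.18) and Tgfb1 (1.92). Macrophage genes rose in 9 of 16 (13 when adjusted over the list alone; adjusted p = 0.611 with an estimated correlation), such as Ccr2 (1.95). In all, edgeR called 8512 of 16949 genes, 4326 higher and 4186 lower, with 1560 rises and 494 falls over 2-fold, and 132 of the 136 named genes counted moved that way in 5 of 5 transgenic libraries. Leaving out any library gave 7761 to 8382 genes.

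Although muscle held few vector counts, some fast-fiber and glycolytic genes rose there with treatment. Fast-fiber genes rose in 3 of 12 (10 up and 1 down when adjusted over the list alone; median 0.31; adjusted p = 0.133 with an estimated correlation): Pvalb (0.77, SE 0.16), Actn3 (0.66, SE 0.13) and Atp2a1 (0.51, SE 0.10). Glycolytic genes rose in 5 of 18 (12 up and 2 down when adjusted over the list alone; adjusted p = 0.211 with an estimated correlation), with Pygm at 0.56 (SE 0.11) and Aldoa at 0.50 (SE 0.10). The chaperones Pdia3 (−0.37) and Hsp90b1 (−0.26) of the unfolded protein response fell (2 of 14; 6 when adjusted over the list alone; adjusted p = 0.211 with an estimated correlation), as did Cthrc1, a marker of matrix-producing fibroblasts (−2.88, SE 0.63; called in 3 of 20 alternatives, with vehicle replicate 3 apart from the others, gap over range 0.785), and the collagen gene Col8a1 (−1.08; 10 of 21). The calls of Pvalb, Actn3 and Atp2a1 held in 10, 11 and 11 of 21 alternatives. The gluconeogenic phosphatase Fbp2 (1.07, SE 0.13) and Tpbgl (1.52, SE 0.22) rose. Extracellular matrix genes had a median of −0.95 (12 falls when adjusted over the list alone and 0 over all genes by edgeR; adjusted p = 0.211 with an estimated correlation), while denervation genes had a median of −0.32 with no gene past the threshold over all genes or when adjusted over the list alone (adjusted p = 0.616 with an estimated correlation).

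By count, 175 genes were called for treatment in muscle (125 higher, 50 lower), and 34 of the 36 named genes counted moved that way in 6 of 6 libraries, with 4 of 6 for Prr32. For 10 of the 36 the treated and vehicle-treated libraries did not overlap. Of the 175, 171 had been called with the opposite sign in transgenic against wild-type muscle, 48 as rises that fell and 123 as falls that rose, and for the 2054 genes that differed over 2-fold there the median share undone was 27.0%. It was 2.62 to 4.63% in 20 simulations with no treatment change, and 11.8 to 24.8% (median 21.8%) with separate vehicle libraries (10 splits), where the treatment change had a median of 0 called genes (0 to 279). The correlation over genes was r = −0.59, and −0.49 with separate vehicle libraries for each change; on log CPM the covariance was −0.157 against −0.0252 simulated. The count rested on single libraries: 1, 1, 12, 10 and 308 without vehicle replicates 1 to 5 in order, and 59, 67, 114, 1 and 28 without treated replicates 2 to 6 in order. DESeq2 called 957 and limma-voom 376, while 4 were called without the sex term, 18 with replicate number as a block and 1 without mice older than 36 weeks. That last setting alone called 0 of the 36 named genes, so 0 of 36 were called in every alternative.

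Treated muscle stayed far from wild type, with 5938 genes called (2951 higher, 2987 lower). Denervation genes were higher in 16 of 19 (16 when adjusted over the list alone; median 2.72; adjusted p = 0.133 with an estimated correlation), and Krt8 outside the list was higher by 7.58 (SE 0.68). Atrophy genes were higher in 11 of 18 (13 up and 1 down when adjusted over the list alone; adjusted p = 0.168 with an estimated correlation), fast-fiber genes lower in 10 of 12 (10 when adjusted over the list alone; median −0.47; adjusted p = 0.231) and oxidative phosphorylation lower in 28 of 30 (29 when adjusted over the list alone; adjusted p = 0.655). Leaving out any library gave 5032 to 6341 genes.

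The tissues differed in which genes parted transgenic from wild-type mice. The transgenic minus wild-type change differed in 2161 of 22316 genes between spinal cord and cortex (4972 at unadjusted p under 0.05), 6914 between spinal cord and muscle and 6182 between cortex and muscle. The treatment change differed in 15, 672 and 571 genes. Spinal cord and muscle still shared 1403 rises and 1021 falls with the transgene over the 16146 genes tested in both, against 851.4 and 750.8 by chance. Prnp, singled out after its values were seen, rose in spinal cord (1.99, SE 0.05) and muscle (3.22, SE 0.13), in all libraries, with a difference between these tissues of −1.26. Atxn7l3b, likewise singled out, fell with treatment in spinal cord (−0.54, adjusted p = 8.7e-08, 6 of 6 libraries), and the difference to muscle, where it was −0.10 (adjusted p = 0.36), was −0.46.

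The sexes were compared by interaction terms. In spinal cord 2074 genes differed between females and males in the transgenic minus wild-type change (559 higher and 1515 lower in females), among them Ahsg, which encodes fetuin-A (7.61, SE 0.99, adjusted p = 0.0115), and Gvin1 (−1.92), both named after their values were seen. Of the 3 vehicle-treated transgenic females, 2 were 39 weeks old and all males 36 weeks, so sex cannot be parted from age there. In muscle 19 genes differed, including the nicotinamide riboside kinase Nmrk2 (2.68, SE 0.37) and Cdkn1c (1.16), also named after their values were seen. There the older vehicle-treated transgenic mouse (39 weeks) was a female too and all males were 36 weeks old, so sex is partly confounded with age. In cortex no gene differed by edgeR (864 at unadjusted p under 0.05; 0 with RLE scaling). The change with treatment differed between the sexes in 0 genes of spinal cord, cortex and muscle by edgeR, with 2805, 1088 and 900 at unadjusted p under 0.05 and 0 in each with RLE scaling.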

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

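The tests below were chosen after the results were seen, except the splits of the samples and the test for shared reads. The weighing covers 3 patterns, and the values that stand apart follow.

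The amiR was directed against Atxn2, yet Atxn7l3b fell with treatment, by a log2 change of −0.54 in spinal cord and −0.39 in cortex, and not detectably in muscle (−0.10, adjusted p = 0.36). The tables argue against shared reads, since the longest stretch the transcripts share is 15 bases, below the read length. A return toward wild type is excluded by the level in treated spinal cord, −0.66 (log2) below wild type. A candidate explanation is a short sequence shared with Atxn2, as a small RNA needs for pairing: of 16377 7-mers scanned, TCTCGAC in 3′ UTRs had the lowest change in spinal cord (z −4.93, 175 genes, mean −0.08, permutation p = 0.01, without Atxn2 and Atxn7l3b), ranked 2 in cortex (z −4.27) and had z 0.32 in muscle, where vector counts were near 0. Atxn2 carries it in coding sequence at chromosome 5 from 121813512 to 121813518, and Atxn7l3b in its 3′ UTR at chromosome 10 from 112926879 to 112926885 (GRCm38). The sequence of the amiR is not given in the sources used here and no arm had a control vector, so an effect of AAV itself stays open.

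Prnp rose in every tissue of transgenic mice (1.99 in spinal cord, 2.2 in cortex, 3.22 in muscle), Thy1 in spinal cord (1.33) and cortex (2.12), and Lamr1-ps1, which lies 4969 bases from Prnp on the same strand, from 0 counts to at least 102-fold higher in spinal cord and at least 72.2-fold in muscle. A rise of the whole region around Prnp was excluded in cortex and spinal cord, where the median change of the tested genes within 500 kb was −0.01. In muscle 7 of 8 neighbours were called, in both directions (median 0.24, from −2.49 to 1.70), where 8512 of all 16949 genes were called. These calls therefore do not decide whether a part of the region rose there by less than Prnp. Human PFN1 and Thy1 varied together over the 12 transgenic libraries of spinal cord (r = 0.95, rho = 0.76, permutation p = 1e-04 and 0.00656, adjusted p of r = 2e-04, r = 0.81 without the 2 farthest) and of cortex (r = 0.96, permutation p = 1e-05, the smallest possible). In 11 muscle libraries human PFN1 varied with Prnp (r = 0.97, rho = 0.86, permutation p = 2e-05 and 0.00121, adjusted p of r = 6e-05, r = 0.98 without the 2 farthest), but not detectably in spinal cord (r = 0.18, permutation p = 0.593) or cortex (r = 0.56, permutation p = 0.0555, adjusted p = 0.0832); 6 such relations were computed. The correlations go with Thy1 sequence in a transgene by spinal cord and cortex, and with Prnp sequence by muscle. A transgene has the same sequence in every tissue, so only its expression can differ between them. Lamr1-ps1 rose beside Prnp in cortex too, at least 104-fold. The weaker correlations leave the source of the Prnp rise in spinal cord and cortex open. The tables argue against a larger share of neurons as the source of the Thy1 rise, since synaptic genes had a median of −0.36 in spinal cord and −0.03 in cortex.

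Treated spinal cord libraries spread along the first principal component from −7.4 to 40: replicates 1 (40) and 3 (30.9) lay within the range of vehicle-treated transgenic libraries, and the other 4 between that range and wild type. Human PFN1 ran against an explanation by a lower transgene level in the tissue as a whole: libraries nearer to wild type held more of it (r = −0.92, rho = −0.89, n = 6, exact p = 0.0111 and 0.0333, adjusted p = 0.0333 and 0.1, r = −0.91 without the 2 farthest, 3 relations). In tissue RNA this level also varies with the share of cells that express the transgene. The correlation therefore does not decide whether the level per cell was lower. The amount of vector cannot be told apart from other differences with 6 libraries (WPRE r = −0.21, rho = −0.09, exact p = 0.726 and 0.919, r = 0.93 without the 2 farthest). RNA quality cannot be told apart either (RIN r = 0.13, rho = 0.26, exact p = 0.776 and 0.658, r = 0.12 without the 2 farthest). Age and sex of the mice stay open as untested.

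Other splits of the libraries into groups of the same sizes, 100 for each comparison with the real one included, were run to ask whether chance can be excluded. In spinal cord 1 of 100 splits, the real one, called as many genes as transgenic against wild type (7442, highest other 16), as treated against vehicle (1017, highest other 612) and as treated against wild type (5163, highest other 2067). The real grouping thus gave more genes than any other grouping drawn. The same holds for treated against wild-type cortex (244, highest other 0) and in muscle for transgenic against wild type (8512, highest other 7017), treated against vehicle (175, highest other 5) and treated against wild type (5938, highest other 10). A share of 1 of 100 is the smallest that these splits can give, and it was not adjusted over the comparisons. The splits were not held to equal numbers of each sex, and they do not cover the dependence of the treatment counts on single libraries. Where the arms differ in size, a grouping that mirrors the real one but for 1 library could also be drawn. Whether the 7017 in muscle came from such a grouping was not tested, so it may not measure what an unrelated grouping calls. In cortex 2 of 100 splits, the real one included, called as many for transgenic against wild type (5, highest other 152) and for treated against vehicle (4, highest other 6). That share is under 0.05, but in each case another split called more genes than the real one. The splits therefore do not exclude chance for these 2 counts, and they do not test single genes. Among the 5 genes, Prnp and Thy1 also rose in transgenic spinal cord (edgeR adjusted p = 1.3e-13 and 1.02e-05). In cortex Nbdy held at least 687 counts in each wild-type library and 11 over all 12 transgenic ones. Lamr1-ps1 held 1 count over the wild-type libraries and at least 272 in each transgenic one. These values argue against chance for these genes and do not cover Mnat1. The split with 152 genes, several times the real count, points to a structure of the cortex samples; which one was not tested.

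Among groups of 5 or 6 libraries, 6 of 120 had a library far from the others (5%), and chance gives about 1 in 20 for independent values. Several of these values come from the same library and are not independent. Spinal cord wild-type replicate 3 held 109.3 M counts (gap over range 0.703), a RIN of 8.3 (0.727), 15.3% of its counts in the top 10 genes (0.652) and 520.6 CPM of Prnp (0.777). Treated spinal cord replicate 2 lay at −60.9 on the second component (0.911), and cortex vehicle replicate 6 held the 1 WPRE count of 0.0127 CPM against 0 (gap over range 1). For the named genes, 94 of 1359 groups (6.92%) had such a library, most often treated spinal cord replicate 2, with 8.

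Differences between tissues and sexes that passed their own interaction tests were as follows. For the transgenic minus wild-type change they numbered 2161 genes between spinal cord and cortex, 6914 between spinal cord and muscle and 6182 between cortex and muscle, and for treatment 15, 672 and 571. Between females and males they numbered 2074 in spinal cord and 19 in muscle, and sex and age are partly confounded in both tissues. Singled out were Pfn1 (0.35, spinal cord minus cortex), Thy1 (−0.82 spinal cord minus cortex, 0.95 spinal cord minus muscle, 1.77 cortex minus muscle), Prnp (−1.26 spinal cord minus muscle, −1.02 cortex minus muscle) and Atxn7l3b (−0.21 spinal cord minus muscle), all for the transgene. For treatment they were Atxn2 (−0.62 spinal cord minus muscle, −0.33 cortex minus muscle) and Atxn7l3b (−0.46 and −0.31 for the same pairs). WPRE was counted in treated muscle at a mean of 0.0303 CPM, against 0 in vehicle-treated and wild-type muscle.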

How the results depend on the processing

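No alternative was chosen after the results were seen. Counts for spinal cord transgenic and treated against wild type, and for muscle transgenic and treated against wild type, stayed within 1.5 times under every alternative, as did all 12 tissue and sex counts under RLE. The directions of the tissue differences did not all hold. For the transgene, spinal cord minus cortex had 1215 higher and 946 lower, but 1053 and 1676 by RLE. Cortex minus muscle had 2843 and 3339, but 3700 and 2709 by RLE. Spinal cord minus muscle kept more lower than higher (3235 and 3679, by RLE 3467 and 3485). RLE scaling kept each of the 9 counts (130 of 200 values over all alternatives were within 1.5 times, 70 were not). Like TMM, RLE takes most genes as unchanged, so it cannot test that assumption. In transgenic against wild-type muscle 8512 of 16949 genes were called, and no ERCC line held a count to scale by. How far the muscle counts and their directions depend on this assumption was not tested.

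For treated against vehicle spinal cord (1017), the count was 2216 by DESeq2, 430 with no filter beyond 1 count, 321 with RIN, 543 with replicate number as a block, 373 with only the 2 arms, 88 without older mice and 0 when 4 libraries followed their library names, which also gave Atxn2 −0.28 (adjusted p = 0.381); leaving out a library gave 237 to 2507. In cortex, transgenic against wild type (5) became 9 by DESeq2 and 4 to 5 without a library. For treated against vehicle cortex (4) it was 340 by DESeq2, 7 with no filter, with RIN or with the block, 2 with at least 1 CPM, 11 without the sex term, 0 with only the 2 arms or without older mice, and 1 to 74 without a library. Treated against wild-type cortex (244) gave 1381 by DESeq2, 35 with no filter, 11 with RIN, 126 with the block, 430 with only the 2 arms, 8 without older mice and 11 to 369 without a library. For treated against vehicle muscle (175) it was 957 by DESeq2, 376 by limma-voom, 265 with at least 1 CPM, 4 without the sex term, 449 with RIN, 18 with the block, 445 with only the 2 arms, 1 without older mice and 1 to 308 without a library. Fewer samples enter without older mice or a library; otherwise the cause was not tested.

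Atxn2 kept its direction and side in 63 of 67 alternatives. Cortex passed by DESeq2 (−0.27, adjusted p = 0.0427), with −0.32 to −0.23 without a library; muscle turned to −0.02 without older mice and ranged from −0.01 to 0.07 without a library; spinal cord ranged from −0.56 to −0.54 without a library, and was −0.57 with RIN or without the 4 libraries with conflicting labels. Pgk1 (0.20 in treated against vehicle spinal cord) turned to −0.03 by library name. The correlation over genes was −0.68, −0.87 and −0.67 in spinal cord, cortex (5 genes) and muscle over genes called for the transgene, −0.56 in spinal cord and −0.65 in muscle with at least 1 CPM, and −0.44, 0.12 (reversed; −0.23 over all cortex genes, weaker than the −0.51 to −0.44 that shared libraries alone gave in simulations) and −0.49 with separate vehicle libraries.

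With an estimated correlation the called lists numbered 1, 0 and 3 in spinal cord (transgenic against wild type, treated against vehicle, treated against wild type), 0, 0 and 1 in cortex and 0, 0 and 0 in muscle. With fry they numbered 0, 3 and 4 in cortex, and 21 and 11 in the first 2 comparisons of muscle. Genes near the floor of 3 counts per library are limited by depth, and no alternative tested depth.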

Other observations

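The gene lists not described above were tested with the others, and the short-sequence values below were seen before they were chosen for printing. In transgenic spinal cord the chaperones of the heat shock response fell in 8 of 13 and rose in 1 (9 and 1 when adjusted over the list alone; median −0.24; adjusted p = 0.501 with an estimated correlation), with Hsph1 at −0.57, Dnajb1 at −0.67 and Hspa1a at −1.68 (SE 0.47). Genes of autophagy and the lysosome rose in 10 of 18 and fell in 3 (11 and 3 when adjusted over the list alone; adjusted p = 0.29 with an estimated correlation), with progranulin Grn at 2.02 (SE 0.19) and Hexa at 1.45. Extracellular matrix genes rose in 8 of 18 and fell in 3 (9 and 3 when adjusted over the list alone; adjusted p = 0.392 with an estimated correlation), with Postn at 4.40 (SE 0.35). The proteasome fell in 13 of 27 (14 when adjusted over the list alone; adjusted p = 0.746 with an estimated correlation), with Psmc5 at −0.34. Genes linked to ALS rose in 4 of 22 and fell in 7 (4 and 8 when adjusted over the list alone) without a list call (camera adjusted p = 0.34), with Ang at 1.91 (SE 0.23) and Tuba4a at −0.55. Oligodendrocyte and excitatory neuron lists gave no call.

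The ATF4 response, the branch of the stress response that induces amino acid synthesis, rose in 5 of 20 with treatment in spinal cord (5 when adjusted over the list alone; adjusted p = 0.307 with an estimated correlation), with the hormone Fgf21 at 5.47 (SE 0.65, adjusted p = 0.000507, 6 of 6 libraries), Chac1 at 0.99 (SE 0.17) and Asns at 0.37. Against wild type, treated spinal cord had Fgf21 at 4.70, and 10 of 20 rose and 1 fell (12 and 1 when adjusted over the list alone; adjusted p = 0.29 with an estimated correlation). In muscle of transgenic mice the ALS gene Chchd10 (−0.92, SE 0.12) and the actin list member Pfn2 (−0.94, SE 0.07) fell, while the small chaperone Hspb8 rose by 1.87 (SE 0.21).

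Nbdy held 1356 to 1632 counts in wild-type spinal cord libraries and 4 counts over the 12 transgenic ones, and in muscle it was at least 157-fold lower in transgenic libraries, all of which held 0 counts. The lowest 7-mer was GTGCCTT in cortex (z −4.64, permutation p = 0.045) and ACATTCC in muscle (z −4.62, permutation p = 0.05). In the 4 spinal cord libraries with conflicting labels, WPRE was 0, 0, 36.4 and 40.1 and Atxn2 106.4, 110.2, 76.3 and 68.2 unscaled CPM for vehicle replicates 5 and 6 and treated replicates 1 and 2.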
